A study of Arabidopsis thaliana with 18 samples.

How the data were processed

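Total RNA of Arabidopsis thaliana roots was sequenced as stranded mRNA libraries with paired reads of 150 bases. The labels place each library in 1 of 6 groups of genotype (WT, C4 or B2) and NaCl concentration (0 or 150 mM). C4 and B2 are, per the labels' protocols, transgenic lines with an isoprene synthase gene of Eucalyptus globulus. The protocols in the labels also describe an empty vector line as the control and 50 and 100 mM NaCl, given for 5 days to seedlings 5 days old, as treatments for growth measurements. The sample labels name WT and 150 mM, which are used here. How plants for the 150 mM libraries were grown is not given in the sources used here, and the file header names 32 alignment files, of which those of the empty vector line and others were not analysed here.

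The deposited table holds raw counts per gene, which the authors made with featureCounts 2.0.3, per the file headers. Reads were counted on exons summed by gene, with strand setting 2 (reverse stranded), a mapping quality of at least 10, and Araport11 gene models, per the file headers. Both reads of a pair were counted separately, so a count is a read and not a fragment. The submitters' processing notes list TAIR10, FastQC 0.12.1, fastp and STAR 2.7.11a. Multi-mapping reads were not counted under these settings, so near-identical gene copies can have counts that are too low. Gene spans are those of the deposited table, in TAIR10 coordinates, and symbols came from a reference gene table for 24528 of 24532 genes; 99.7% of the spans were equal to the reference. Gene length was deposited beside the counts and was not used in any test.

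WT libraries 1 and 2 at 0 mM held equal counts in 24515 of 24532 genes. The 17 genes that differed lay among the first 28 rows, 13 of them by exactly 1 digit, and no other pair of libraries had more than 2993 equal genes. The mean chi-square per gene between both columns was 0.0667. Library 1 was kept and library 2 was left out, so WT at 0 mM had n = 3. The 17 genes were left out of all tests. The tests had been planned with 18 samples, and 17 libraries entered them. Total counts were 54233853 to 91527683 per library, with 21291 to 21602 genes detected and 3.97% to 5.64% of the counts in the 10 highest genes.

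Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, its filter on low counts and a robust quasi-likelihood fit of 1 mean per group over all 17 libraries, which share the estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment over 21367 genes and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. Means and SDs are of CPM on TMM-scaled library sizes, and log2 CPM for principal components and list tests used a prior count of 2. No batch or pairing is given in the labels, so there was no covariate. To test the procedure, counts were simulated with 200 changed genes per comparison. Each gene was drawn independently from its mean over all libraries and its fitted dispersion, without variation that a whole library shares. The report gives the share recovered.

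There were 27 gene lists, with 411 of 417 written members kept; 3 were not in the table and 3 had another name in the reference. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and, as an alternative, an estimated one, adjusted over the lists of a comparison, and a list needed 5 measured members. On simulated data with 1 moved list, that list was called and 0 of the others were. Genes were drawn independently there, so this could not show false calls that arise when genes of a list vary together. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 8 genes per direction with the largest change among called genes with a mean of at least 5 CPM whose libraries did not overlap between groups, up to 4 members per list with the lowest adjusted p, and always RBCS1A, RD29A, RD29B, P5CS1, SOS1, HKT1 and NCED3. The rule was applied per comparison, so a gene given for some genotypes only may also have changed in the others. Genes named outside the rule are said to be.

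The alternatives were DESeq2's size factors in edgeR, no filter on low counts, DESeq2 1.42.0 as the test, only the groups compared in the fit, and leaving out each library in turn. Chosen after seeing the data were counting the near-identical column as a library and leaving out libraries whose levels of ANNAT3 or MRD1 went against their labels, or that lay closest to a library of another group. Gene lists, their medians and the overlap of the salt responses with each library left out were also added after seeing the data; in the overlap, genotypes without that library kept their calls. The test of a wrong label for B2 0 mM library 3 first asked for a closest library of WT at an SD of log2 ratios below that of any pair within a group, which was met. It was made stricter after C4 and B2 0 mM libraries 2 were seen to lie below that bar as well, and then decided nothing. Comparisons of both lines with the same WT libraries were set beside 50 simulated data sets without differences. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.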

Results

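Root RNA of Arabidopsis thaliana was sequenced in wild type (WT) and in lines C4 and B2, which carry an isoprene synthase gene from Eucalyptus globulus. Isoprene is a small volatile made from precursors of the plastid MEP pathway, and Arabidopsis does not emit it naturally. Per the labels, the introduced gene was placed behind the promoter of RBCS1A, the gene of a Rubisco small subunit. Roots came from plants given 0 or 150 mM NaCl, and the comparisons ask how the lines and WT differed in each condition and in their response to salt. The table held 18 columns, of which WT libraries 1 and 2 at 0 mM held equal counts in 24515 of 24532 genes. They differed by less than the sampling noise and were counted as 1 sample, which left 17 libraries. WT had 3 libraries at 0 mM and 2 at 150 mM, and each line had 3 in each condition. Libraries held 54233853 to 91527683 counts, and 21367 genes were tested. The labels do not say that libraries came from separate plants, so p-values measure the spread between these libraries, which may be technical.

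The level of ANNAT3, a gene of the annexin family of calcium-binding proteins, separated B2 from the other genotypes except in 1 library. ANNAT3 (AT2G38760, chromosome 2, 16200944 to 16202669, TAIR10) lay between 59.3 and 180 CPM in the 11 WT and C4 libraries and between 0.458 and 1.36 CPM in 5 of the 6 libraries labelled B2. The library labelled B2 0 mM, library 3, held 96.8 CPM. MRD1 (AT1G53480, chromosome 1, 19963047 to 19964712) lay between 32.8 and 44.0 CPM in 11 of the 12 libraries labelled C4 or B2 and between 0.0965 and 2.06 CPM in 4 of the 5 libraries labelled WT. The library labelled B2 0 mM, library 3, held 0.0499 CPM of MRD1, and the library labelled WT 150 mM, library 2, held 33.4 CPM. HEI10 (AT1G53490, chromosome 1, 19963267 to 19966952), which overlaps MRD1 on the other strand and acts in meiotic crossover formation, held 2.33 to 4.72 CPM in those 4 WT libraries, 8.76 CPM in WT 150 mM library 2, and 1.70 CPM in B2 0 mM library 3. Counting was strand-specific. These 3 genes were chosen after their values were seen. Neither the introduced gene nor isoprene was analysed here, so the values of ANNAT3 and MRD1 are the measured facts that go against the labels of these 2 libraries, and each direction between genotypes below includes both libraries as labelled.

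**Figure D1:**
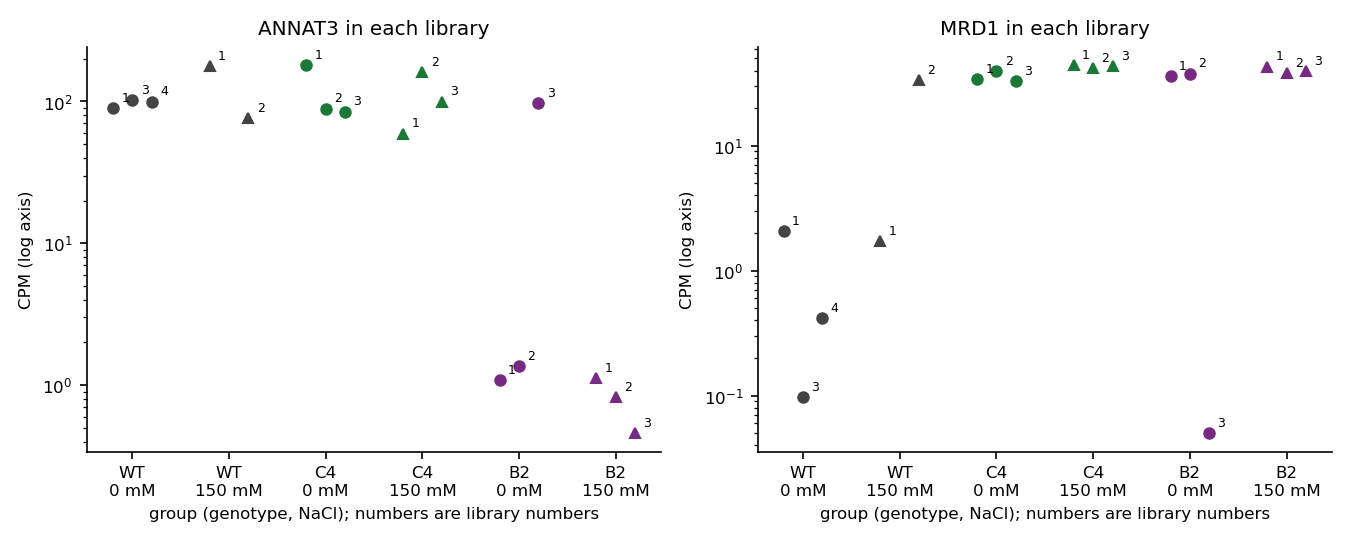
ANNAT3 (left) and MRD1 (right) in CPM on log axes, 1 point per library, by genotype and NaCl concentration, with library numbers beside the points. ANNAT3 was at 96.8 CPM in B2 0 mM library 3 against 0.458 to 1.36 CPM in the other B2 libraries, and MRD1 was at 33.4 CPM in WT 150 mM library 2 against 0.0965 to 2.06 CPM in the other WT libraries.

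Salt separated the libraries on the first principal component of log2 CPM, which held 41.6% of the variance. Libraries at 0 mM scored between -72.3 and -22.7 and those at 150 mM between 10.9 and 78.1. On the second component, with 8.3% of the variance, WT 150 mM library 1 scored 61.4, and WT 0 mM library 3 and B2 0 mM library 3 scored 36.0 and 36.2. Each of the other libraries scored 5.2 or less.

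**Figure D2:**
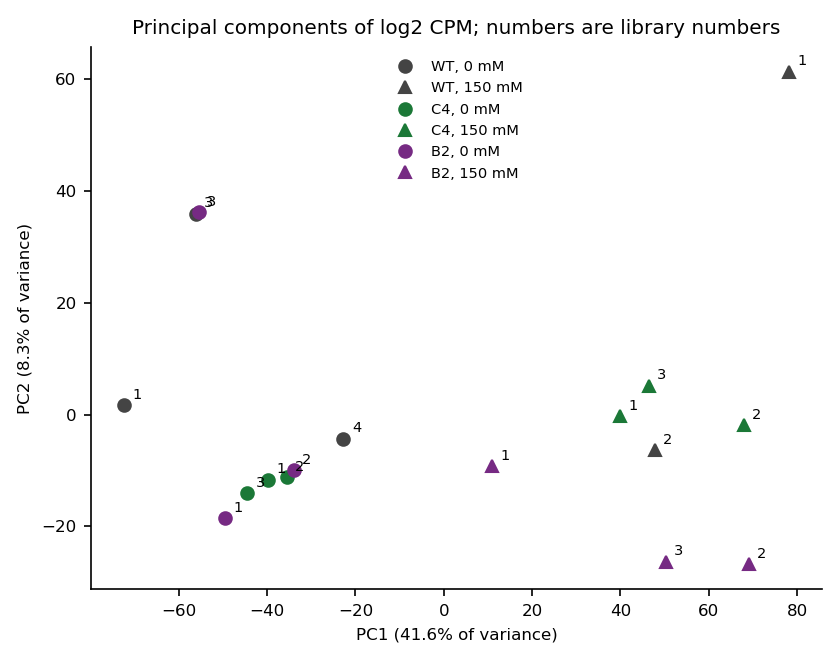
Scores of the 17 libraries on the first and second principal components of log2 CPM (41.6% and 8.3% of the variance). Colours give the genotype, circles 0 mM and triangles 150 mM NaCl, and numbers the library; the 8 libraries at 150 mM lie at 10.9 or above on the first component.

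In WT, 150 mM NaCl raised genes of dehydration tolerance. LEA7, which encodes a late embryogenesis abundant protein, rose 101-fold, from 3.61 ± 3.02 to 364 ± 242 CPM (SD, n = 3 and 2), a log2 fold change of 6.66 ± 0.91 (SE, adjusted p = 0.0012). The LEA family gene AT3G17520 rose 90.4-fold, the ABA-signalling phosphatase gene HAI3 89.2-fold and RD29B (LTI65) 74.4-fold. These folds rest on few libraries: without WT 150 mM library 1 they were 53.5 for LEA7, 42.6 for AT3G17520, 24.4 for HAI3 and 40.9 for RD29B. Without WT 0 mM library 4 they were 174 for LEA7 and 259 for RD29B, and without WT 150 mM library 2, 139 for AT3G17520 and 155 for HAI3. Among the genes that fell, AT4G37290 went from 28.9 ± 9.54 to 0.739 ± 0.53 CPM (log2 fold change -5.29 ± 1.12, adjusted p = 0.00768), the class III peroxidase gene AT1G49570 from 28.6 ± 15.8 to 2.09 ± 0.122 CPM, and CYP81F2, which modifies indole glucosinolates, from 324.5 ± 47.0 to 31.2 ± 28.1 CPM. AT4G37290 and CYP81F2 did not pass without WT 150 mM library 1 (log2 fold changes -4.70 and -2.67), and had -6.29 and -4.83 without library 2. In total, 1984 genes rose and 1571 fell by edgeR's quasi-likelihood test, 954 and 697 of them by at least 2-fold. The count of 3555 depended on single libraries: it was 330 without WT 150 mM library 1, 1761 without WT 0 mM library 1 and 2217 without WT 0 mM library 3, and 992 with only the groups compared in the fit.

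In C4, the same treatment raised RD29B 46.3-fold, from 3.07 ± 1.34 to 143 ± 71.6 CPM (n = 3 and 3; log2 fold change 5.53 ± 0.97, adjusted p = 0.00341). AT3G17520 rose 40.2-fold, the galactinol synthase gene GOLS2 (GolS2) 38.4-fold, LEA7 34.3-fold, HAI3 31.3-fold and TSPO, which encodes an ABA-induced membrane protein, 27.8-fold. LEA7 rose 57.6-fold without C4 0 mM library 2 and HAI3 19.3-fold without C4 150 mM library 2. AT1G49570 fell by 3.02 ± 0.63 on the log2 scale. The cell wall genes XTH13 and EXT10 fell by 2.98 ± 0.45 and 2.77 ± 0.50 on that scale. In total, 1430 genes rose and 1162 fell by edgeR's test, 666 and 518 of them by at least 2-fold. The count of 2592 was 1310 without C4 150 mM library 2, 1360 without C4 0 mM library 3, 1441 without C4 0 mM library 1 and 1454 without C4 150 mM library 3.

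In B2, RD29B rose 48.8-fold under 150 mM NaCl, from 2.31 ± 2.22 to 113 ± 62.6 CPM (n = 3 and 3; log2 fold change 5.61 ± 0.97, adjusted p = 0.00442). GOLS2 rose 46.4-fold, LEA7 44.8-fold, TSPO 36.6-fold, HAI3 33.7-fold and AT3G17520 31.8-fold. Without B2 0 mM library 2 the folds were 110 for RD29B, 72.6 for GOLS2, 58.0 for TSPO and 51.0 for AT3G17520, and without B2 150 mM library 2 they were 30.3 for GOLS2, 24.1 for TSPO and 22.3 for HAI3. AT4G37290 fell from 21.7 ± 10.7 to 1.43 ± 1.44 CPM (log2 fold change -3.90, and -5.16 without B2 150 mM library 1). MSRB7, a methionine sulfoxide reductase gene, fell from 338.7 ± 66.1 to 38.3 ± 20.4 CPM, and the monodehydroascorbate reductase gene MDHAR from 466.2 ± 78.0 to 87.8 ± 35.3 CPM. In total, 2054 genes rose and 1417 fell by edgeR's test, 726 and 379 of them by at least 2-fold. The count of 3471 was 1299 without the library labelled B2 0 mM, library 3, which held WT levels of ANNAT3, and 1843 without B2 0 mM library 1. It was 5728, 703 and 1174 without B2 150 mM libraries 1, 2 and 3.

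Genes induced by abscisic acid (ABA) and dehydration rose as a group in each genotype. Of 30 measured members, 29 rose in WT, 28 in C4 and 28 in B2, and adjusted over the list alone the counts were 29, 29 and 28. RD29A (LTI78, AT5G52310, chromosome 5, 21240717 to 21243644) rose from 59.9 ± 38.5 to 2135 ± 816 CPM in WT, from 87.4 ± 27.99 to 1864 ± 977 CPM in C4 and from 73.2 ± 22.3 to 2141 ± 1166 CPM in B2, with log2 fold changes of 5.16 ± 0.64, 4.41 ± 0.60 and 4.87 ± 0.62. The dehydrin gene ERD10 rose by 2.96 ± 0.37, 2.88 ± 0.35 and 2.93 ± 0.35 on that scale. RD29A rose 35.7-fold in WT, and 55.5-fold without WT 0 mM library 4. RD22, an ABA-induced gene, rose by 2.74 ± 0.31 in C4 and 2.36 ± 0.30 in B2. Genes were named per comparison, so here and elsewhere a gene given for some genotypes only may also have changed in the others. The median log2 fold change of the list was 3.17 in WT, 2.65 in C4 and 2.47 in B2. Set tests with the preset correlation gave adjusted p = 2.05e-27, 3.6e-28 and 1.05e-23, and adjusted p = 0.358, 0.124 and 0.29 with an estimated correlation. No list passed the threshold with an estimated correlation in any of the comparisons. Without WT 150 mM library 1, 17 members rose in WT over all genes and 29 adjusted over the list alone.

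Genes of carotenoid and ABA synthesis rose alongside, 8 of 19 measured members in WT, 9 in C4 and 6 in B2, and 10, 9 and 10 adjusted over the list alone. NCED3 (AT3G14440, chromosome 3, 4831286 to 4834015), whose product cleaves carotenoids in the step that limits ABA synthesis, rose from 14.2 ± 7.13 to 133.8 ± 96.7 CPM in WT, from 15.7 ± 2.64 to 92.6 ± 36.4 CPM in C4 and from 14.3 ± 4.05 to 71.9 ± 30.02 CPM in B2. The phytoene synthase gene PSY rose 2.201-fold in WT and 1.99-fold in C4, ABA1 rose 3.77-fold in WT and 4.03-fold in B2, and ZDS about as far in C4 and B2 (2.00-fold and 1.96-fold). In the proline and compatible solute list, 6, 6 and 7 of 14 members rose (6, 6 and 9 adjusted over the list alone). P5CS1 (AT2G39800, chromosome 2, 16598072 to 16603319), the rate-limiting enzyme of proline synthesis, rose 9.30-fold in WT, 5.87-fold in C4 and 5.54-fold in B2, and 5.81-fold in WT without WT 150 mM library 1. Without that library NCED3 did not pass in WT (4.61-fold, adjusted p = 0.0612), and without WT 150 mM library 2 it rose 14.4-fold. The sucrose synthase gene SUS1 rose 7.54-fold, 6.63-fold and 7.12-fold. Adjusted p with the preset correlation was 6.68e-06, 1.95e-06 and 9.96e-05 for ABA synthesis and 0.000818, 0.000523 and 6.64e-05 for solutes; with an estimated correlation it was adjusted p = 0.358, 0.124 and 0.333 for ABA synthesis and adjusted p = 0.463, 0.334 and 0.333 for solutes. In WT, 2 ABA synthesis genes rose without WT 150 mM library 1, and without the library labelled B2 0 mM, library 3, 4 solute genes rose in B2.

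**Figure D3:**
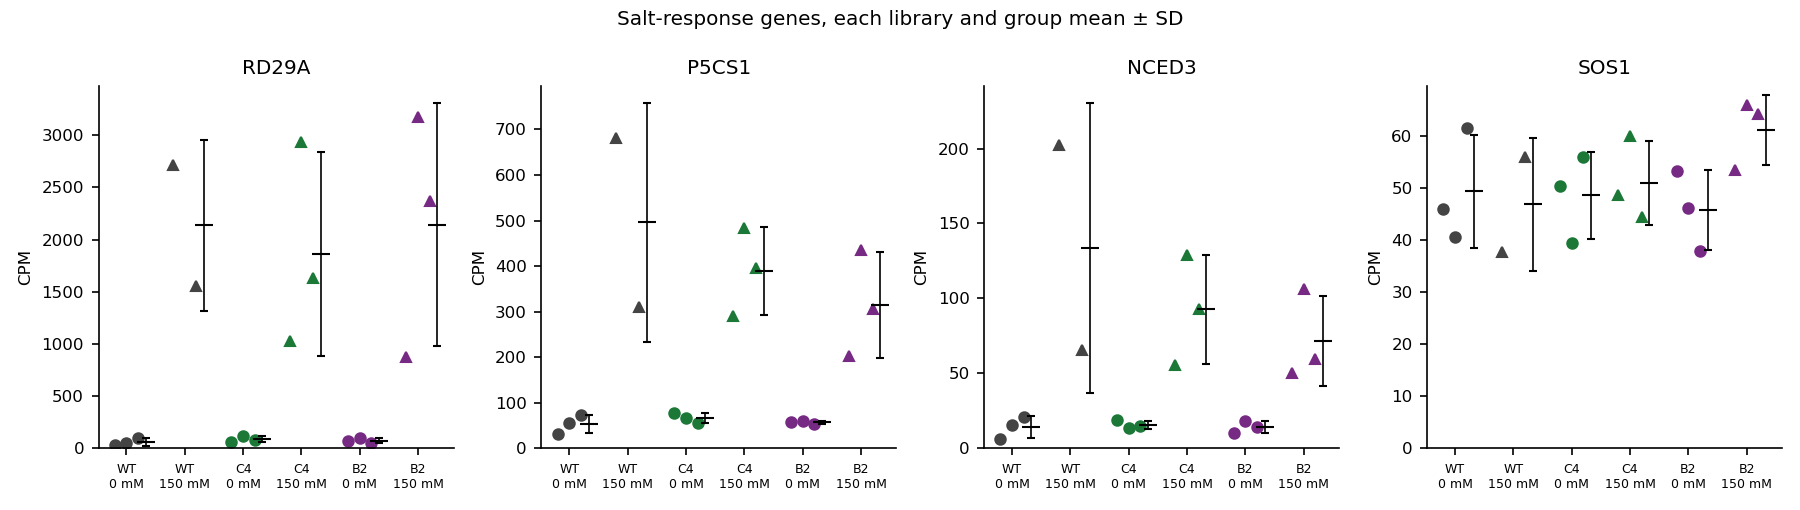
RD29A, P5CS1, NCED3 and SOS1 in CPM, 1 point per library (circles 0 mM, triangles 150 mM NaCl), with the group mean and SD as black bars. RD29A, P5CS1 and NCED3 were higher at 150 mM than at 0 mM in each genotype, and SOS1 was at 46.9 ± 12.8 CPM in WT at 150 mM against 49.3 ± 10.8 CPM at 0 mM.

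Of the ion transporter genes, few members passed the test. In the sodium and potassium transport list of 20 members, 2 rose in WT, 1 rose and 2 fell in C4, and 2 rose and 1 fell in B2 (1 and 0, 1 and 2, and 3 and 1 adjusted over the list alone). GORK, an outward potassium channel of root cells and guard cells, rose 3.26-fold, 3.47-fold and 3.41-fold in WT, C4 and B2. SLAH1, an anion channel homologue, fell by 1.08 ± 0.26 on the log2 scale in C4 and by 0.91 ± 0.26 in B2. SOS1, the sodium/proton exchanger of the plasma membrane, had log2 fold changes of -0.07 ± 0.21, 0.07 ± 0.19 and 0.42 ± 0.19, and HKT1, a sodium transporter of the root vasculature, of 0.26 ± 0.23, -0.13 ± 0.21 and -0.38 ± 0.21, none past the threshold. RBCS1A (AT1G67090, chromosome 1, 25048158 to 25049667) had log2 fold changes of 0.66 ± 0.40, -0.04 ± 0.36 and -0.74 ± 0.37, also not past it. The set test gave adjusted p = 0.346, 0.675 and 0.0993 for this list. In WT, 1 gene rose without WT 150 mM library 1, and 1 rose and 2 fell without library 2; in B2, 1 rose without the library labelled B2 0 mM, library 3.

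Root hair genes fell, 7 of 14 members in WT, 9 in C4 and 5 in B2, and 9, 11 and 8 adjusted over the list alone. EXPA18, an expansin gene of root hairs, fell by 1.00 ± 0.20, 1.65 ± 0.18 and 0.94 ± 0.18 on the log2 scale in WT, C4 and B2. LRX1 fell by 0.97 ± 0.26, 1.85 ± 0.23 and 0.78 ± 0.22, and PRP3 by 1.36 ± 0.32, 2.01 ± 0.28 and 0.92 ± 0.27; both encode wall proteins of root hairs. The list had adjusted p = 0.00279, 1.96e-10 and 0.000635 with the preset correlation and adjusted p = 0.476, 0.124 and 0.394 with an estimated correlation. Suberin genes of the endodermis rose, 4, 4 and 7 of 9 members (5, 7 and 7 adjusted over the list alone). GPAT5 rose 2.49-fold, 2.02-fold and 2.11-fold and KCS2 2.06-fold, 1.83-fold and 2.07-fold; adjusted p for the list was 0.00332, 0.000523 and 6.91e-05, and adjusted p = 0.476, 0.334 and 0.333 with an estimated correlation. No Casparian strip gene of 7 measured passed the threshold by edgeR in any genotype, and adjusted over the list alone the counts were also 0 (set test adjusted p = 0.841, 0.433 and 0.659). In the cell cycle and meristem list of 16 members, 3, 1 and 2 fell (4, 1 and 4 adjusted over the list alone), among them SHR, a regulator of root patterning, by 0.56 ± 0.16, 0.52 ± 0.14 and 0.42 ± 0.14 on the log2 scale. That list had adjusted p = 0.0247, 0.00695 and 0.000635, and adjusted p = 0.608, 0.535 and 0.466 with an estimated correlation. In WT, 0 root hair, suberin or cell cycle genes passed by edgeR without WT 150 mM library 1, and 0 cell cycle genes without library 2. In B2, 2 suberin and 0 cell cycle genes passed without the library labelled B2 0 mM, library 3.

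Genes of indole glucosinolate synthesis fell, 5 of 8 members in WT, 6 in C4 and 7 in B2 (6, 7 and 8 adjusted over the list alone; set test adjusted p = 0.00321, 1e-05 and 1.18e-05, and adjusted p = 0.445, 0.124 and 0.29 with an estimated correlation). UGT74B1 fell by 0.69 ± 0.18, 0.94 ± 0.16 and 0.92 ± 0.16 on the log2 scale and SUR1 by 0.60 ± 0.16, 0.73 ± 0.14 and 0.82 ± 0.14. In the phenylpropanoid and flavonoid list of 13 members, 4, 3 and 4 fell and 1 rose in each genotype (4, 4 and 5 fell and 1 rose adjusted over the list alone). The chalcone synthase gene TT4 fell by 1.62 ± 0.34, 1.32 ± 0.29 and 1.46 ± 0.29, the flavonol synthase gene FLS1 fell by 1.82 ± 0.40 in WT and 1.49 ± 0.34 in B2, and the phenylalanine ammonia-lyase gene PAL4 rose 2.12-fold, 1.8-fold and 2.17-fold. Set tests for that list gave adjusted p = 0.0227, 0.329 and 0.192, and in WT adjusted p = 0.476 with an estimated correlation. In WT, 0 glucosinolate genes and 1 flavonoid gene fell without WT 150 mM library 1, and 1 of each without library 2. In B2, 2 flavonoid genes fell without the library labelled B2 0 mM, library 3.

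The isoprenoid pathways that share precursors with isoprene held few called genes. In the MEP pathway list of 11 members, 2 rose in WT, 1 in C4 and 3 in B2, equal to the counts adjusted over the list alone, and the set test gave adjusted p = 0.159, 0.195 and 0.369. DXR rose 1.499-fold, 1.39-fold and 1.35-fold, but no longer passed when any 1 of 3 libraries in WT, 5 in C4 or 4 in B2 was left out. HDR, which encodes the last enzyme of the pathway, rose 1.75-fold in WT and 1.95-fold in B2. In the mevalonate and sterol list of 12 members, 2 fell in each genotype (2, 4 and 2 adjusted over the list alone), with HMGS lower by 0.79 ± 0.16, 0.75 ± 0.14 and 0.64 ± 0.14 on the log2 scale. That list had adjusted p = 0.217, 0.0307 and 0.104, and in C4 adjusted p = 0.48 with an estimated correlation. In WT, 0 genes of either list passed without WT 150 mM library 1 and 1 of each without library 2; in B2, 0 MEP genes and 1 mevalonate gene passed without the library labelled B2 0 mM, library 3.

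Among hormone genes, members of a list went both ways. In the salicylic acid and defence list of 13 members, 1 rose in each genotype and 3, 1 and 2 fell (1, 2 and 1 rose and 6, 2 and 3 fell adjusted over the list alone). FRK1, a receptor kinase gene used as a marker of immune signalling, rose 2.56-fold, 3.01-fold and 3.74-fold, whereas WRKY33 fell by 0.97 ± 0.20 on the log2 scale in WT and 0.89 ± 0.17 in B2, and CBP60G fell by 2.74 ± 0.59 in C4 and 1.85 ± 0.57 in B2. In the auxin list of 22 members, 3, 2 and 2 rose and 3, 2 and 2 fell, with the same numbers adjusted over the list alone. The auxin-conjugating enzyme gene GH3.5 (WES1) rose 3.53-fold, 2.01-fold and 3.28-fold and the auxin carrier gene LAX3 fell by 1.19 ± 0.18, 0.92 ± 0.16 and 0.86 ± 0.16. GA2OX6, a gibberellin-inactivating enzyme gene, rose 1.84-fold, 1.84-fold and 1.81-fold, as 1 of the 3, 5 and 1 of 12 gibberellin genes that rose (3, 5 and 1 rose and 0, 1 and 0 fell adjusted over the list alone). In the ethylene list of 13 members, 3 rose and 1 fell in each genotype (5, 4 and 3 rose and 1 fell adjusted over the list alone). In the jasmonate list of 23 members, 2, 3 and 1 rose and 1, 1 and 3 fell (2, 3 and 1, and 1, 2 and 6, adjusted over the list alone), and in the cytokinin list of 15 members, 2, 2 and 1 rose and 1, 4 and 0 fell (3, 3 and 1, and 3, 5 and 0, adjusted over the list alone). Of these lists, salicylic acid passed the set test in WT (adjusted p = 0.0247), ethylene in C4 (0.0182), gibberellin in C4 and B2 (0.0307 and 0.045) and jasmonate in B2 (0.0167). With an estimated correlation these were adjusted p = 0.476, 0.283, 0.124, 0.29 and 0.607. With WT 150 mM library 1 left out, 0 ethylene, gibberellin, jasmonate or cytokinin genes passed in WT, and 0 salicylic acid genes and 1 auxin gene fell. With library 2 left out instead, 7 jasmonate genes rose and 0 fell, 0 salicylic acid genes rose and 7 fell, and 2 ethylene and 2 cytokinin genes fell. In B2 without the library labelled B2 0 mM, library 3, 0 ethylene and 0 gibberellin genes rose, 1 salicylic acid and 1 auxin gene fell, and 11 jasmonate genes fell adjusted over the list alone.

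Nutrient genes fell in part. In the iron deficiency list of 16 members, 3 fell in WT, 4 in C4 and 1 in B2 (4, 4 and 1 adjusted over the list alone). OPT3, an iron transporter gene, fell by 1.90 ± 0.30 on the log2 scale in WT and 1.59 ± 0.25 in C4, F6'H1 (AT3G13610), which makes coumarins secreted under iron shortage, fell by 2.18 ± 0.51 and 1.49 ± 0.42 (in WT by 1.55, not past the threshold, without WT 150 mM library 1 and by 3.32 without library 2), and MYB10 fell by 1.15 ± 0.32 in B2. Of 11 nitrate genes, 4 fell in WT, 0 in C4 by edgeR (set test adjusted p = 0.576) and 2 in B2, and adjusted over the list alone 4, 0 and 2 fell and 1, 0 and 2 rose. The nitrate reductase gene NIA1 fell from 817 ± 78.2 to 219.6 ± 108 CPM in WT and the nitrite reductase gene NIR1 from 754 ± 145 to 275.7 ± 150.2 CPM, with log2 fold changes of -1.89 and -1.45, and of -2.50 and -2.14 without WT 150 mM library 2. UPM1 fell by 1.29 ± 0.27 on the log2 scale in WT and 0.74 ± 0.23 in B2, and NRT1.8 by 1.62 ± 0.41 in B2. In the phosphate starvation list of 10 members, 2 rose in each genotype and 2 fell in WT (3, 2 and 2 rose and 3, 1 and 0 fell adjusted over the list alone), with the phosphatase gene PAP17 up 3.62-fold, 3.25-fold and 3.17-fold. The iron list passed the set test in C4 (adjusted p = 0.042) and the nitrate list in WT (adjusted p = 0.0169), with adjusted p = 0.535 and adjusted p = 0.476 with an estimated correlation; phosphate had adjusted p = 0.898, 0.995 and 0.0681. In WT, 1 iron, 0 nitrate and 0 phosphate genes fell without WT 150 mM library 1, and 7 nitrate and 4 phosphate genes fell without library 2. In B2, 0 nitrate genes fell without the library labelled B2 0 mM, library 3.

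Of 18 aquaporin genes, 4 rose and 2 fell in WT, 2 rose and 3 fell in C4, and 1 rose and 2 fell in B2 (5 and 3, 2 and 3, and 1 and 2 adjusted over the list alone; set test adjusted p = 0.315, 0.183 and 0.503). PIP1B, a plasma membrane water channel gene, rose 2.35-fold, 1.83-fold and 1.799-fold, and DELTA-TIP, a tonoplast one, fell by 1.07 ± 0.22, 1.06 ± 0.19 and 1.16 ± 0.19 on the log2 scale. In the list of reactive oxygen and antioxidant genes, 1, 2 and 1 of 25 rose and 6, 1 and 6 fell (1, 3 and 2, and 7, 6 and 6, adjusted over the list alone; adjusted p = 0.255, 0.967 and 0.277). GSTU24 fell by 1.45 ± 0.22 in WT and the catalase gene CAT1 rose 2.93-fold in C4. Hypoxia genes included 2, 3 and 3 of 10 that rose and 1 that fell in WT, with the same counts adjusted over the list alone. The alcohol dehydrogenase gene ADH1 rose 7.36-fold, 7.56-fold and 6.54-fold and PDC1 (AT4G33070) 1.92-fold in C4 and 1.70-fold in B2; the set test gave adjusted p = 0.264, 0.00578 and 0.0275, and in C4 and B2 adjusted p = 0.334 and adjusted p = 0.466 with an estimated correlation. Of 9 heat shock genes, 1 fell in WT (HSP70, by 0.77 ± 0.24), 2 rose in C4 and 1 fell in B2 (HSFA2, by 1.55 ± 0.45, and by 2.25 without B2 150 mM library 1), and 1 fell, 2 rose and 2 fell adjusted over the list alone. HSP17.6C (AT1G53540) rose 3.498-fold in C4, with 5.73 and 7.02 CPM in C4 150 mM libraries 1 and 3 and 1.49 CPM in library 2. That list had adjusted p = 0.486, 0.484 and 0.0144, and in B2 adjusted p = 0.466 with an estimated correlation. In WT without WT 150 mM library 1, 0 aquaporin and 0 heat shock genes passed, 0 reactive oxygen genes rose and 1 fell, and 0 hypoxia genes fell. No heat shock gene passed there without library 2 either. In B2 without the library labelled B2 0 mM, library 3, 1 aquaporin, 3 reactive oxygen and 0 heat shock genes fell, and 4 heat shock genes fell adjusted over the list alone.

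Few genes of photosynthesis, fixed as markers of shoot tissue, passed the test for salt. Of 22 members, 4 rose in WT, 0 passed in C4 by edgeR and 1 rose in B2, and 5, 0 and 0 rose adjusted over the list alone. LHCA4 rose from 35.7 ± 21.5 to 90.8 ± 7.68 CPM in WT and from 34.3 ± 9.58 to 70.8 ± 18.4 CPM in B2, and LHCB4.1 and RCA rose 2.53-fold and 1.78-fold in WT. The count in WT ranged from 0 to 15 with 1 library left out, and without WT 0 mM library 4 LHCA4 rose 3.90-fold and LHCB4.1 4.08-fold. The set test gave adjusted p = 6.38e-05, 0.183 and 0.0148, and in WT and B2 adjusted p = 0.476 and adjusted p = 0.668 with an estimated correlation. No member passed in WT without WT 150 mM library 1 or without library 2, nor in B2 without the library labelled B2 0 mM, library 3. None of 8 common reference genes passed the threshold by edgeR in any genotype, also adjusted over the list alone (adjusted p = 0.894, 0.813 and 0.503), and 1 fell in WT without WT 150 mM library 2.

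Most list counts for salt moved when 1 library was left out. Each such fit also has fewer libraries, so a lost call need not mean a changed level. Of the named genes that passed for salt, 15 of 49 in WT had folds that moved by over 1.5 times. In C4 and B2 these were 2 of 45 and 7 of 49. Of the lists with members that rose, leaving out 1 library moved the count by over 1.5 times in 14 of 18 in WT, 11 of 18 in C4 and 11 of 18 in B2, and of those with members that fell in 17 of 17, 10 of 14 and 15 of 15. The ABA response counts ranged from 17 to 29, 25 to 28 and 20 to 28. Root hair counts ranged from 0 to 7 in WT, 8 to 10 in C4 and 1 to 5 in B2, suberin counts from 0 to 4, 0 to 6 and 0 to 7, and glucosinolate counts from 0 to 5, 4 to 5 and 2 to 7. Of the genes named here that passed for salt, 31 of 49 in WT, 14 of 45 in C4 and 21 of 49 in B2 no longer passed without at least 1 library. The libraries whose absence ended the most calls were WT 150 mM library 1 (30), B2 150 mM libraries 2 and 3 (21 and 17), B2 0 mM libraries 1 and 3 (12 each) and C4 150 mM library 2 (12).

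**Figure D4:**
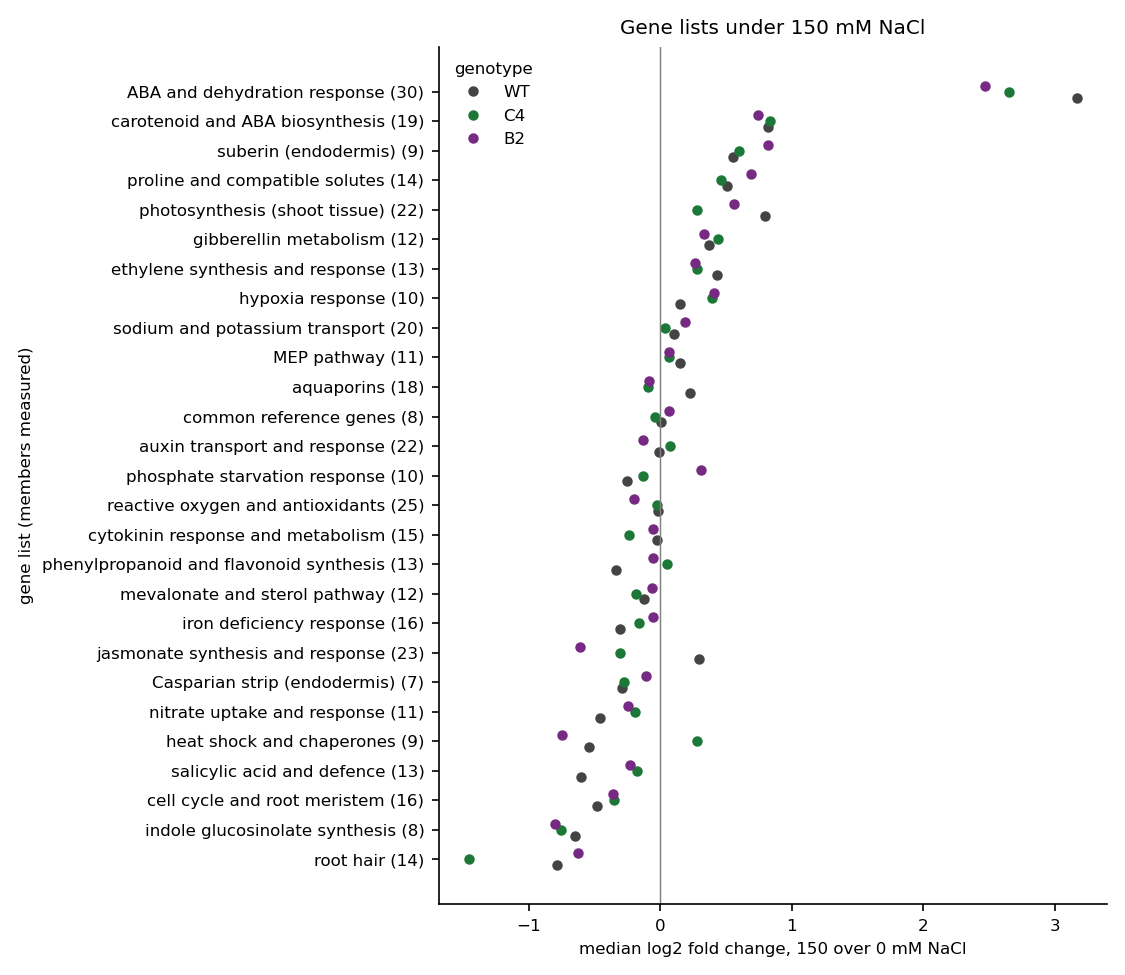
Median log2 fold change of each of the 27 gene lists at 150 over 0 mM NaCl (x axis) in WT, C4 and B2, with the number of measured members beside the list's name. The ABA and dehydration list lay highest at 3.17, 2.65 and 2.47, and the root hair list lowest in WT and C4 at -0.79 and -1.45.

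The salt responses of the genotypes overlapped. Across 21367 genes, which are not independent replicates, log2 fold changes had Pearson's r of 0.619 between WT and C4, 0.618 between WT and B2 and 0.565 between C4 and B2. WT and C4 shared 1062 genes that rose and 734 that fell, where independent lists would share 133 and 85, and none was called in opposite directions. WT and B2 shared 1187 and 771 genes (191 and 104 for independent lists), and C4 and B2 shared 990 and 660 (137 and 77), with 1 gene called in opposite directions in each of these pairs. In all 3 genotypes, 842 genes rose and 508 fell, of 5562 called in at least 1. These counts depended on single libraries: they were 217 and 62 without WT 150 mM library 1, 355 and 178 without B2 150 mM library 2, 529 and 276 without B2 150 mM library 3, and 442 and 315 without C4 150 mM library 2. They were 462 and 396 without C4 0 mM library 3, 539 and 374 without C4 0 mM library 1, and 501 and 335 without the library labelled B2 0 mM, library 3. With 1 library left out, the genes shared by WT and C4 ranged from 226 to 1101 and from 68 to 780, those shared by WT and B2 from 234 to 1416 and from 72 to 975, and those shared by C4 and B2 from 375 to 1104 and from 200 to 763.

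At 0 mM NaCl, no gene passed the threshold between C4 and WT. MRD1 lay between 32.8 and 39.4 CPM in the 3 C4 libraries and between 0.0965 and 2.06 CPM in the 3 WT libraries, and HEI10 between 6.92 and 9.17 CPM and between 2.33 and 2.64 CPM. Their log2 differences were 5.40 ± 1.47 and 1.73 ± 0.41 (SE; adjusted p = 1 by edgeR). These genes were named after their values were seen, and the fit's estimate of the spread includes the libraries labelled B2 0 mM, library 3, and WT 150 mM, library 2, which belong to neither group. Without both, MRD1, HEI10 and AT3G12320 passed, with adjusted p = 0.0473, 0.000505 and 0.03. In the planned fit of only the groups compared, which also holds neither library, 0 genes passed. The libraries were left out for their MRD1 and ANNAT3 levels, so a smaller spread of MRD1, and of HEI10, which overlaps it, follows from that choice and is not independent evidence. RBCS1A stood at 25.2 ± 10.4 CPM in C4 and 32.7 ± 15.0 CPM in WT (n = 3 and 3; log2 difference -0.38 ± 0.36), RD29A at 87.4 ± 27.99 and 59.9 ± 38.5 CPM, and P5CS1 at 66.3 ± 10.4 and 53.4 ± 19.9 CPM. The log2 differences of NCED3, SOS1 and HKT1 were 0.15 ± 0.47, -0.02 ± 0.19 and 0.04 ± 0.21. In the flavonoid list, 2 of 13 genes were lower in C4 when adjusted over the list alone and 0 over all genes, with 4CL3 at 14.7 ± 2.72 against 33.9 ± 10.1 CPM and FLS1 at 72.5 ± 9.72 against 159.3 ± 46.4 CPM. That count ranged from 0 to 6 with 1 library left out. Set tests with the preset correlation passed for 6 lists: ABA response (median log2 difference 0.31), jasmonate (0.34) and photosynthesis (0.37) higher in C4, and flavonoid (-0.33), aquaporin (-0.19) and reactive oxygen genes (-0.09) lower. With an estimated correlation these gave adjusted p = 0.933, 0.933, 0.933, 0.665, 0.691 and 0.665. With 1 library left out, the medians ranged from 0.14 to 0.76, 0.04 to 0.52, 0.08 to 0.90, -0.57 to -0.18, -0.26 to -0.14 and -0.14 to -0.06. The photosynthesis median was lowest without WT 0 mM library 1 and highest without WT 0 mM library 4, in which GAPA was at 20.6 CPM, against 4.79 and 7.02 CPM in WT libraries 1 and 3 and 7.90 to 14.4 CPM in C4; GAPA was named after its values were seen. The count of genes was 0 by edgeR, with 868 genes at an unadjusted p under 0.05 where 1068 would be met by chance, and 7 by DESeq2. In simulated data of this comparison, 71 of 100 genes changed 2-fold and 88 of 100 changed 4-fold were recovered. Simulated genes were drawn independently, without variation that a whole library shares, so these shares may be too high for the real data. The count of 0 therefore does not show that few genes changed 2-fold.

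Between B2 and WT at 0 mM NaCl, no gene passed the threshold either. RBCS1A stood at 24.4 ± 10.99 CPM in B2 and 32.7 ± 15.0 CPM in WT (n = 3 and 3; log2 difference -0.42 ± 0.36), and RD29A, P5CS1 and NCED3 had log2 differences of 0.29 ± 0.53, 0.09 ± 0.33 and 0.02 ± 0.47. SOS1 and HKT1 had -0.11 ± 0.19 and 0.21 ± 0.21. The B2 mean of RBCS1A rests on unlike values. It was at 18.3 and 17.8 CPM in libraries 1 and 2 and at 37.1 CPM in the library labelled B2 0 mM, library 3. Set tests with the preset correlation passed for 8 lists, with jasmonate (median log2 difference 0.40), ABA response (0.22), heat shock (0.48) and photosynthesis (0.12) higher in B2, and flavonoid (-0.24), aquaporin (-0.19), phosphate (-0.26) and cytokinin genes (-0.08) lower. In that order they gave adjusted p = 0.358, 0.768, 0.364, 0.768, 0.358, 0.358, 0.358 and 0.358 with an estimated correlation, and no member passed adjusted over the list alone. Without the library labelled B2 0 mM, library 3, 5 of 13 flavonoid genes were lower adjusted over the list alone (median log2 difference -0.59), and 1 aquaporin gene was higher and 1 lower; the medians of the heat shock, photosynthesis and cytokinin lists were then 0.72, 0.31 and -0.13. Leaving out WT 0 mM library 1 gave medians of -0.06, -0.21 and -0.03 for the ABA response, photosynthesis and cytokinin lists, and leaving out WT 0 mM library 4 gave 0.56, 0.75 and -0.19. The jasmonate median was 0.25 and the aquaporin median -0.13 without B2 0 mM library 1, and the flavonoid median -0.12 without B2 0 mM library 2. The count of genes was 0 by edgeR (315 at an unadjusted p under 0.05, 1068 by chance) and 0 by DESeq2. Without the library labelled B2 0 mM, library 3, 4 genes passed: ANNAT3 (log2 difference -6.31 ± 0.62), HEI10 (1.72 ± 0.22), AT3G12320 (1.39 ± 0.20) and AT5G07310 (3.88 ± 0.58); these genes were named after their values were seen, and ANNAT3 is 1 of the genes for which the library was doubted.

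At 150 mM NaCl, aquaporin genes stood lower in C4 than in WT when tested as a list. Of 18 members, 16 lay below WT, 13 of them past the threshold adjusted over the list alone and 0 over all genes (median log2 difference -0.50; preset adjusted p = 2.79e-11, adjusted p = 0.0837 with an estimated correlation). RD28, a plasma membrane aquaporin gene, stood at 97.2 ± 11.7 CPM in C4 and 176.5 ± 7.77 CPM in WT (n = 3 and 2; log2 difference -0.86 ± 0.15) and PIP1C at 453 ± 42.4 and 695 ± 59.1 CPM. At 0 mM RD28 was also lower, at 113 to 126 CPM in C4 and 140 to 156 CPM in WT. The list's median ranged from -0.64 to -0.41 with 1 library left out. Without WT 150 mM library 1 the list alone gave 1 lower member and without WT 150 mM library 2, which held MRD1 at the level of the lines, 2. In the nitrate list, 3 of 11 genes were higher adjusted over the list alone (preset adjusted p = 0.000934, adjusted p = 0.437 with an estimated correlation), with NIA1 at 767 ± 341 against 219.6 ± 108 CPM and NIR1 at 680 ± 177 against 275.7 ± 150.2 CPM. NIA1 was at 809, 407 and 1090 CPM in C4 libraries 1, 2 and 3 and at 143 and 296 CPM in WT libraries 1 and 2, and NIR1 at 711, 489 and 840 CPM and at 169 and 382 CPM. The nitrate count was 0 without WT 150 mM library 1 (median 0.03) and 6 without WT 150 mM library 2. Heat shock genes were higher in 3 of 9 (preset adjusted p = 1.73e-05, adjusted p = 0.211 with an estimated correlation), with HSP17.4 at 11.7, 5.63 and 13.9 CPM in C4 libraries 1, 2 and 3 and 3.11 ± 0.0384 CPM in WT.

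Root hair genes had a median log2 difference of -0.47 in C4 against WT at 150 mM, with 1 of 14 lower adjusted over the list alone (preset adjusted p = 2.35e-07, adjusted p = 0.211 with an estimated correlation) and EXPA7 at 22.1 ± 5.52 against 38.7 ± 0.194 CPM. Adjusted over the list alone, 3 of 15 cytokinin genes, 1 of 20 ion transport genes and 1 of 8 reference genes were lower and 2 of 10 hypoxia genes higher. In all 5 lists with lower members, these included, the count moved by over 1.5 times for at least 1 library left out. Cytokinin, salicylic acid and hypoxia lists also passed with the preset correlation (medians -0.19, 0.18 and 0.38) and gave adjusted p = 0.24, 0.437 and 0.366 with an estimated correlation. The salicylic acid median was -0.08 without WT 150 mM library 1 and 0.84 without library 2. The cytokinin median was -0.32 and -0.13 without these, in that order, and -0.08 without C4 150 mM library 3. The root hair median was -0.25 without WT 150 mM library 2. The cytokinin and hypoxia counts were 0 and the root hair count 3 without WT 150 mM library 1, and the root hair count was 0, with 4 salicylic acid genes higher, without library 2. The potassium channel gene SKOR stood at 7.97 ± 1.73 against 14.2 ± 0.89 CPM and HKT1 at 10.4 ± 1.47 against 13.2 ± 1.09 CPM. RBCS1A had a log2 difference of -1.07 ± 0.40, and RD29A, P5CS1, NCED3 and SOS1 of -0.20 ± 0.58, -0.35 ± 0.36, -0.53 ± 0.52 and 0.12 ± 0.22. None of these genes passed over all genes: the count was 0 by edgeR (1377 at an unadjusted p under 0.05) and 57 by DESeq2. It was 56 without WT 150 mM library 2 and 30 without C4 150 mM library 2.

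**Figure D5:**
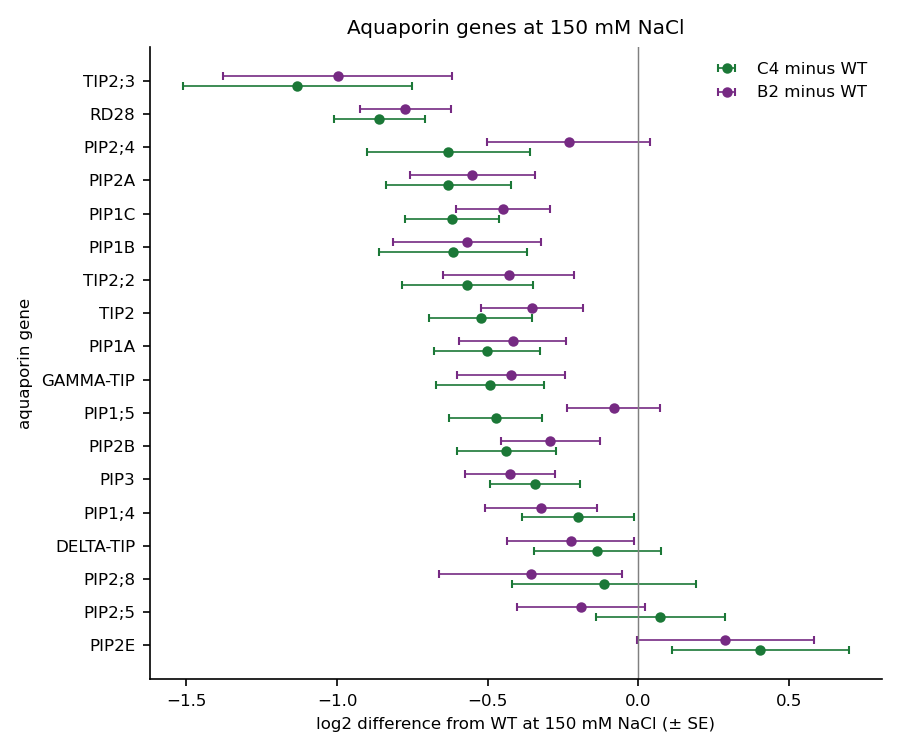
Log2 difference from WT at 150 mM NaCl of 18 aquaporin genes in C4 and B2, with SE bars (x axis, log2 of the fold difference). Of the 18 genes, 16 lay below WT in C4, 17 in B2 and 16 in both lines at once, and none passed the threshold over all genes. Both lines were compared with the same WT libraries, and genes of a list are not independent, so their agreement is not repeated evidence.

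In B2 at 150 mM NaCl, 17 of 18 aquaporin genes lay below WT, with 1 past the threshold adjusted over the list alone and 0 over all genes (median log2 difference -0.39; preset adjusted p = 6.74e-07, adjusted p = 0.358 with an estimated correlation). That gene was RD28, at 103 ± 5.87 CPM in B2 and 176.5 ± 7.77 CPM in WT (n = 3 and 2; log2 difference -0.77 ± 0.15), and PIP1C stood at 509 ± 73.3 and 695 ± 59.1 CPM. The aquaporin median ranged from -0.51 to -0.34 with 1 library left out. Of 11 nitrate genes, 3 were higher adjusted over the list alone (preset adjusted p = 0.00419, adjusted p = 0.967 with an estimated correlation), with log2 differences of 1.46 ± 0.42 for NIA1, 1.23 ± 0.32 for NIR1 and 0.81 ± 0.29 for NIA2. That count was 0 without WT 150 mM library 1 (median -0.09) and 6 without WT 150 mM library 2. RBCS1A stood at 14.6 ± 2.18 CPM against 51.5 ± 9.90 CPM in WT (log2 difference -1.82 ± 0.40) and CASP5, a Casparian strip membrane protein gene, at 9.15 ± 0.851 against 24.3 ± 0.254 CPM. RD29A, P5CS1, NCED3, SOS1 and HKT1 had log2 differences of 0.00 ± 0.59, -0.66 ± 0.36, -0.90 ± 0.52, 0.38 ± 0.22 and -0.43 ± 0.23. Adjusted over the list alone, 1 gene each of the carotenoid, photosynthesis, Casparian strip and cell cycle lists was lower, and none without WT 150 mM library 1. When library 2 was left out instead, 5 jasmonate genes were lower and 3 salicylic acid and 3 iron genes higher. The ABA response list passed with the preset correlation (median -0.38) and gave adjusted p = 0.967 with an estimated correlation. Its median was 0.18 without WT 150 mM library 1 and -0.76 without library 2, and the aquaporin count reached 12 with 1 library left out. No gene passed over all genes by edgeR (count 0, with 2154 at an unadjusted p under 0.05), and 27 did by DESeq2. Without WT 150 mM library 2 the count was 495, resting on WT 150 mM library 1 alone, whose spread was then assumed to be that of the other groups.

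C4 and B2 were each compared with the same WT libraries, which raises the overlap of their differences with no effect at all. Across genes at 0 mM, in a fit of the 3 groups, the log2 differences of C4 and B2 from WT had r = 0.629, against a mean of 0.498 (0.472 to 0.53) in 50 simulated data sets with no difference, and a covariance of 0.0824 against a simulated mean of 0.0603 and maximum of 0.0662. At 150 mM they had r = 0.602 against 0.611 (0.567 to 0.645) and a covariance of 0.1854 against a mean of 0.1076 and maximum of 0.121. In each condition 0 genes were shared by edgeR, where independent lists would share 0 and simulated data 0.02 and 0.04 on average. The simulated sets shared their controls in the same way. The WT libraries could not be split so that each part kept at least 2, so part of the excess may still come from the shared controls. Simulated counts were drawn independently per gene and lack variation that the genes of a library share. The excess therefore cannot be read as an effect of the lines.

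No gene passed the test of a difference in salt response between either line and WT. RD29A had a difference of log2 fold changes of -0.74 ± 0.78 in C4 and -0.29 ± 0.79 in B2, P5CS1 of -0.66 ± 0.49 and -0.75 ± 0.49, NCED3 of -0.68 ± 0.70 and -0.91 ± 0.70, and RBCS1A of -0.70 ± 0.54 and -1.40 ± 0.54. For C4 minus WT the count was 0 by edgeR, with 775 genes at an unadjusted p under 0.05, and 6 by DESeq2. For B2 minus WT it was 0 by edgeR, with 967, and 1 by DESeq2, and for the mean of both lines 0, with 867, and 1 by DESeq2. By list, 1 nitrate and 1 hypoxia gene in C4 were higher and 4 of 23 jasmonate genes in B2 lower adjusted over the list alone, and 0 over all genes. For the mean of both lines, 1 nitrate and 1 reactive oxygen gene were higher adjusted over the list alone. That comparison had 0 nitrate genes higher and 4 jasmonate genes lower without the library labelled B2 0 mM, library 3, and 0 genes of either list passed without WT 150 mM library 1. It had 6 nitrate and 4 salicylic acid genes higher and 7 jasmonate genes lower without WT 150 mM library 2, and 0 reactive oxygen genes without either of these WT libraries. The jasmonate count in B2 was 7 without the library labelled B2 0 mM, library 3 (median -0.83), 10 without WT 150 mM library 2 (median -1.04) and 0 without WT 150 mM library 1 (median -0.06). The nitrate count in C4 was 0 without library 1, as was the hypoxia count. It was 4 in C4 and 6 in B2 without library 2, with 5 and 4 salicylic acid genes higher. In simulated data of C4 minus WT, 27 of 100 genes changed 2-fold and 74 of 100 changed 4-fold were recovered. Simulated genes were again drawn independently, so these shares may also be too high. Without WT 150 mM library 2 the counts were 2, 95 and 62, and without C4 150 mM library 2 the count for C4 was 8.

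C4 and B2, which carry the same introduced gene per the labels, were also compared with each other. At 150 mM NaCl, 5 of 9 heat shock genes were higher in C4 adjusted over the list alone and 0 over all genes (median log2 difference 1.03; preset adjusted p = 5.12e-08, adjusted p = 0.186 with an estimated correlation). HSP17.6C stood at 4.75 ± 2.89 CPM in C4 and 1.16 ± 0.357 CPM in B2 and HSP17.4 at 10.4 ± 4.27 and 4.21 ± 1.23 CPM (n = 3 and 3). The higher values were those of C4 libraries 1 and 3: HSP17.6C was at 5.73 and 7.02 CPM in them and at 1.49 CPM in C4 library 2, below B2 library 1 and above 0.791 CPM in B2 library 2. HSP17.4 was at 11.7 and 13.9 CPM and at 5.63 CPM, beside 5.48 CPM in B2 library 1. The jasmonate synthesis gene LOX4 stood at 9.27 ± 6.07 against 2.45 ± 1.06 CPM and the ethylene synthesis gene ACS2 at 23.4 ± 8.32 against 10.4 ± 2.76 CPM. Adjusted over the list alone, 3 of 13 ethylene, 1 jasmonate and 1 salicylic acid gene were higher in C4 and 1 cytokinin and 1 mevalonate gene lower. Each of these counts moved by over 1.5 times for at least 1 library left out. With 1 library left out, the heat shock count ranged from 3 to 8 and its median from 0.74 to 1.73, the ethylene count from 0 to 2 and the jasmonate median from 0.11 to 0.52. The root hair list was lower in C4 (median -0.48; preset adjusted p = 1.82e-07, adjusted p = 0.287 with an estimated correlation) and the jasmonate list higher (median 0.33, adjusted p = 0.887 with an estimated correlation). The count over all genes was 0 by edgeR (1404 at an unadjusted p under 0.05) and 89 by DESeq2, and it was 37 without C4 150 mM library 2. At 0 mM it was 0 by edgeR (272 at an unadjusted p under 0.05) and 1 by DESeq2, and 1, ANNAT3, without the library labelled B2 0 mM, library 3. At 0 mM the photosynthesis, suberin and iron lists were higher in C4 with the preset correlation (medians 0.26, 0.28 and 0.48), with adjusted p = 0.904 for each with an estimated correlation. The photosynthesis and iron medians were 0.06 and 0.20 without the library labelled B2 0 mM, library 3, the photosynthesis median was -0.10 without C4 0 mM library 2 and 0.43 without B2 0 mM library 1, and the suberin median was 0.11 without C4 0 mM library 1.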

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

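The tests of mislabelling, mixing, second deposits and library state, and the regroupings of libraries, were chosen only after the result was seen; the list tests of the salt response were planned.

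The difference in salt response between C4 and WT passed the list test at the preset correlation for 9 lists, as medians of the log2 difference. These were ABA response (-0.625), photosynthesis (-0.651), root hair (-0.578), aquaporins (-0.316), reactive oxygen (0.092), salicylic acid (0.251), flavonoid (0.301), nitrate (0.369) and heat shock genes (0.518). Between B2 and WT it passed for 8 lists: ABA response (-0.685), jasmonate (-0.597), aquaporins (-0.235), photosynthesis (-0.189), iron (0.255), salicylic acid (0.412), phosphate (0.425) and nitrate genes (0.576). With an estimated correlation, adjusted p lay between 0.383 and 0.708 for the C4 lists and between 0.756 and 0.81 for the B2 lists. Without B2 0 mM library 3, the B2 medians of photosynthesis and iron genes were -0.411 and 0.151. With WT 150 mM library 1 left out, salicylic acid, nitrate and heat shock genes had 0.058, -0.001 and 0.297 in C4, and salicylic acid, nitrate, iron and photosynthesis genes 0.102, 0.026, 0.101 and -0.377 in B2. When WT 150 mM library 2 was left out, ABA response, salicylic acid, flavonoid, photosynthesis, root hair and nitrate genes had -1.109, 0.901, 0.107, -0.329, -0.334 and 1.05 in C4. ABA response, jasmonate, salicylic acid, photosynthesis, iron and nitrate genes then had -1.154, -1.037, 0.841, 0.012, 1.159 and 0.99 in B2. Photosynthesis genes had -0.289 in C4 and 0.062 in B2 without WT 0 mM library 1, and -1.167 and -0.874 without WT 0 mM library 4. In C4, root hair genes had -0.918 without WT 0 mM library 1, heat shock genes 0.291 without C4 150 mM library 3 and reactive oxygen genes 0.057 without C4 150 mM library 1.

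The library labelled B2 0 mM, library 3, held ANNAT3 at 96.8 CPM and MRD1 at 0.0499 CPM, the levels of WT. A mix of B2 and WT RNA is argued against by MRD1 at 0.135% of the mean of the other B2 libraries at 0 mM, and a second deposit of WT 0 mM library 3 by a mean chi-square per gene of 9.58, against 0.0667 for the near-identical pair of columns. The SD of log2 ratios to its closest library, WT 0 mM library 3, was 0.1598, below the lowest value within any group (0.243). C4 and B2 0 mM libraries 2 also lay below it (0.2267) with ANNAT3 at 89.0 and 1.36 CPM. An SD below that bar alone therefore does not decide whether a WT sample carries a B2 label. That second pair was less close, with a mean chi-square per gene of 39.9. Apart from the near-identical columns, the lowest value of any other pair was 34.3, between C4 150 mM libraries 1 and 3. RD28, chosen after its values were seen, was at 148 CPM in B2 0 mM library 3. It was at 97.7 and 108 CPM in B2 0 mM libraries 1 and 2 and at 140 to 156 CPM in WT at 0 mM. WT 0 mM library 3 and B2 0 mM library 3 also scored alike on the second principal component (36.0 and 36.2). A WT sample under a B2 label stays open, as do plants of the B2 line that had lost the introduced gene, which were not tested.

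The library labelled WT 150 mM, library 2, held MRD1 at 33.4 CPM, the level of the lines. Its ANNAT3 level of 76.0 CPM argues against a B2 sample under this label. A mislabelled C4 sample could not be excluded: the SD of log2 ratios was 0.3174 to the closest C4 library at 150 mM, 0.2892 to its closest library, which was of B2, and 0.4483 to WT 150 mM library 1. In this library RD28 was at 171 CPM and RBCS1A at 44.5 CPM. WT 150 mM library 1 held 182 and 58.5 CPM of them. The C4 libraries at 150 mM held 86.2 to 109 CPM and 21.8 to 29.7 CPM. Both genes lay nearer to WT here, whereas MRD1 and HEI10 lay at the level of the lines. RD28 was named with this library counted as WT, and RBCS1A overlapped between C4 and WT at 0 mM. These values therefore do not decide. A biological difference among WT plants stays open as well, untested.

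Without WT 150 mM library 2, 56 genes differed between C4 and WT and 495 between B2 and WT at 150 mM, with WT 150 mM library 1 as the only WT library. That library scored 61.4 on the second principal component, against 5.2 or less for the other libraries at 150 mM, so a state of this library other than its genotype and a difference of the lines cannot be told apart with 1 library. It also scored highest on the first component, which separated the NaCl levels, at 78.1. B2 150 mM library 1 scored 10.9 there. The libraries at 150 mM were thus spread widely on that component, which limits each comparison of genotypes at 150 mM. Without WT 150 mM library 1 the ABA list had median differences in salt response of 0.05 in C4 and -0.03 in B2, and the jasmonate list of -0.06 in B2. An effect of the introduced gene may still be part of the pattern, and that was not tested.

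The 6 libraries of a comparison can be split in 10 ways, so the share of splits with as many genes is never under 0.1. For salt in C4 the real split gave 2592 genes and the highest other 0, and for salt in B2 it gave 3471 and the highest other 0, so 1 of 10 splits reached the real count in each. Each other split mixed 0 and 150 mM libraries in both of its groups. The salt difference then added to the spread within groups, so the counts of 0 do not measure chance. For C4 against WT at 0 mM and C4 against B2 at 0 mM the real split and the highest other gave 0 genes by edgeR (868 and 272 at an unadjusted p under 0.05, and 7 and 1 by DESeq2). For B2 against WT at 0 mM the real split gave 0 and the highest other 73, and for C4 against B2 at 150 mM 0 and 279 (315 and 1404 for the real splits at an unadjusted p under 0.05, and 0 and 89 by DESeq2). With a real count of 0 no split can give fewer, so in these 4 comparisons the number of splits says nothing on chance. The splits with 73 and 279 genes put WT 0 mM libraries 1 and 3 with B2 0 mM library 3, and C4 150 mM libraries 1 and 3 with B2 150 mM library 1, and point to a structure of the samples other than their groups. In the split with 279 genes, these libraries scored 39.9, 46.4 and 10.9 on the first principal component. The other C4 and B2 libraries at 150 mM scored 50.2 to 69.0.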

How the results depend on the processing

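The alternatives that count the near-identical column as a library, or leave out B2 0 mM library 3 with WT 150 mM library 2 or with WT 0 mM library 3, were tests chosen only after the result was seen. Of 204 named gene values, 143 passed the threshold, all of them for salt; 77 of these passed in all alternatives other than those, 66 were lost in at least 1 and 0 reversed. With DESeq2's size factors 203 of 204 values kept their side of the threshold and direction, and without a filter 202. No paired analysis was possible because replicate numbers were given in accession order and pair no libraries. Where an arm kept 1 library, its spread was taken from the other groups. The cause was not tested for any change of a count or direction, and depth was at least 54233853 counts per library.

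With 1 library left out, counts ranged from 330 to 4540 for salt in WT, 1310 to 1984 in C4 and 703 to 5728 in B2. They ranged from 0 to 4 for B2 against WT at 0 mM, 0 to 56 and 0 to 495 for C4 and B2 against WT at 150 mM, 0 to 8, 0 to 95 and 0 to 62 for the salt response of C4, B2 and their mean minus WT, 0 to 1 and 0 to 37 for C4 against B2 at 0 and 150 mM, and 0 to 52 for the overlap of both lines at 150 mM. DESeq2 called 7, 57 and 27 genes for C4 at 0 mM and C4 and B2 at 150 mM against WT, 6, 1 and 1 for the salt responses minus WT, and 1 and 89 for C4 against B2. With only the groups compared in the fit, counts were 992 for salt in WT, 1 for B2 against WT and 1 for C4 against B2 at 150 mM. An estimated correlation left 0 of 27 lists in each comparison, where the preset one called 6, 8, 7 and 3 against WT, 11, 12 and 12 for salt, 9, 8 and 8 for the salt responses minus WT, and 3 and 3 for C4 against B2.

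Without B2 0 mM library 3 and WT 150 mM library 2, counts were 3 and 4 for C4 and B2 against WT at 0 mM, 78 and 544 at 150 mM, 1438 for salt in B2, 2, 54 and 49 for the salt responses minus WT, 1 and 2 for C4 against B2, and 3 and 74 for the overlaps at 0 and 150 mM. Lists called were 6 for B2 against WT at 150 mM and 5 for its salt response minus WT. Without WT 0 mM library 3 and B2 0 mM library 3, counts were 2143 and 1093 for salt in WT and B2, and 1 each for B2 against WT at 0 and 150 mM and C4 against B2 at 0 and 150 mM.

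Directions turned only for values not past the threshold. RD29A in B2 against WT at 150 mM was -0.01 without a filter, -0.01 with only the groups compared and -0.36 without B2 0 mM library 3 and WT 150 mM library 2. SOS1 was 0 for C4 against WT at 0 mM with 18 columns and 0.01 for B2 against WT at 0 mM without B2 0 mM library 3 and WT 150 mM library 2. With 1 library left out, RD29A ranged from -0.05 to 0.92 for B2 at 0 mM, -0.68 to 0.26 for C4 and -0.41 to 0.46 for B2 at 150 mM, and -0.93 to 0.17 for the salt response of B2 minus WT. P5CS1 ranged from -0.17 to 0.36 for B2 at 0 mM, -0.82 to 0.33 for C4 and -1.14 to 0.01 for B2 at 150 mM, and -1.14 to 0.02 for the salt response of C4 minus WT. NCED3 ranged from -0.20 to 0.51 and -0.33 to 0.38 for C4 and B2 at 0 mM, -1.14 to 0.51 and -1.51 to 0.13 at 150 mM, and -1.28 to 0.36 and -1.53 to 0.12 for their salt responses minus WT. SOS1 ranged from -0.37 to 0.18 and -0.06 to 0.19 for salt in WT and C4, -0.15 to 0.16 and -0.23 to 0.08 for C4 and B2 at 0 mM, and -0.13 to 0.42 for C4 at 150 mM. HKT1 ranged from -0.01 to 0.42 for salt in WT and from -0.22 to 0.20 and -0.06 to 0.36 for C4 and B2 at 0 mM, and RBCS1A from -0.27 to 0.34 for salt in C4.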

Other observations

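The genes and tests in this part were chosen only after the result was seen.

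C4 150 mM libraries 1 and 3 stood apart from the other libraries at several genes. ABCG40, a transporter gene, was at 78.6 and 98.0 CPM in them and between 1.70 and 15.3 CPM in the 15 others. BHLH92 was at 7.04 and 9.09 CPM, CYP715A1 at 9.94 and 14.0 CPM and LHT7 at 7.06 and 8.92 CPM. In C4 150 mM library 2 these genes were at 3.02, 0.488, 0.177 and 0.547 CPM.

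Without B2 0 mM library 3 and WT 150 mM library 2, the genes called between C4 and WT at 0 mM were MRD1 (log2 difference 5.39 ± 0.67), HEI10 (1.73 ± 0.16) and AT3G12320 (chromosome 3, 3923515 to 3925502; 1.35 ± 0.18, SE). Between B2 and WT they were MRD1 (5.46 ± 0.69), HEI10 (1.72 ± 0.17), AT3G12320 (1.39 ± 0.20) and ANNAT3 (-6.31 ± 0.56). Both libraries were left out for their MRD1 or ANNAT3 levels, so the calls of these genes, and of HEI10, which overlaps MRD1, are not independent evidence in either comparison. Neither library belongs to the comparison of C4 with WT, where leaving them out only changed the estimate of the spread. In the fit of only C4 and WT at 0 mM, which also holds neither library, 0 genes passed.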
